A study of Mus musculus with 27 samples.

How the data were processed

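RNA of FACS-sorted intratumoral neutrophils and macrophages was measured in 27 libraries of 8 groups, made per the labels' protocols from 10 ng of total RNA with the Ovation RNA-seq V2 and Encore Rapid systems and sequenced on a HiSeq 1500. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.11, Partek 6.6, R 3.3.1, DESeq2 and build mm10. Which tool made which step is not given in the sources used here. The labels number no replicates, so numbers follow the order of the samples and pair nothing. Nothing says whether libraries come from separate mice, so p-values measure only the spread between these samples, which may be technical.

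The deposited values are a signal, read counts the authors divided by a size factor per library. In each library the values of 1000 and above are whole multiples of what 1 read is worth, within 0.02 reads, and 9533 cells are listed at 1. A value of 1 is the lowest listed, so fold changes against it depend on the pseudocount. Many smaller values lost their decimal point: 245864 of 269892 cells (91.1%) had a form that allows it. The place was recovered by requiring whole reads, which left 183560 cells (68.0%) with several possible places, and by a negative binomial model of each gene over the groups that gave each place a probability. The 15650 cells (5.80%) with a probability under 0.95 were left out. The model expected 1.34% of all cells to be wrong. Of all cells 99.7% gave the printed form again, but a wrong place can do so too, so this does not test the places. The design was fixed without foreseeing this damage; the test it names for linear normalised values was used.

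The decoding was tested on simulated libraries with the real genes and group sizes, printed in the same damaged form. Of the cells kept, 0.0552% were wrong in neutrophils and 0.0343% in macrophages, against 65.5% and 65.9% of cells taken as printed. For simulated anti-CSF-1R against control, with 200 genes changed in each cell type, the test recovered 88% of 4-fold and 35% of 2-fold changes in neutrophils, and 75% and 25% in macrophages. For the macrophage combination against anti-CSF-1R it recovered 61% and 10%, and for the macrophage interaction 40% and 4%. False calls were 19 of 142 in neutrophils and 7 of 107 in macrophages. The decoding that uses the groups, with uncertain cells left out, was chosen from an earlier draw of this simulation before the real calls were seen. It can still place a gene's point by group. Calls are also given for decoding without the groups, where a shared mean can hide differences and power was not simulated.

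Genes with at least 10 in at least 2 libraries of the cell type were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), the 4 groups of a cell type in 1 fit and all 8 groups in 1 fit for comparisons between cell types. The Benjamini-Hochberg threshold was an adjusted p of 0.05. The 33 gene lists were fixed before the data were examined and tested with limma's camera at a correlation between genes of 0.01, where a list had at least 3 measured members, adjusted over the lists of a comparison. Of 182 calls 24 held with an estimated correlation, and that p is given beside each list. Members that passed are counted with p adjusted over all genes tested and over the measured members of the list alone. A list's level in a library is the mean log2 deviation of its members from their mean over the cell type. Named genes were up to 10 each way (5 in the other comparisons) with the largest fold change among genes past the threshold, without overlap between the groups and with a mean of at least 5 on the log2 scale; the genes with the smallest p where fewer than 5 passed; the 4 members of each called list with the smallest p; and fixed markers. The text names part of these, chosen after their values were seen. A result for 1 gene among them is not reported here. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Positions are from GENCODE vM21.

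Replicate libraries correlated at 0.926 to 0.972 across genes and none was a copy of another. In macrophages the first principal component (34.0% of variance) put the 4 anti-CSF-1R and combination libraries at 34.9 to 51.7 and the other 8 at -33.7 to 0.748. In neutrophils combination replicate 2 (62.0 on the first component) and cisplatin replicate 2 (48.3 on the second) stood apart. The 10 most abundant genes took 13.4% to 26.6% of a library. Alternatives fixed beforehand covered the pseudocount, the filter, the scaling, the libraries in the fit, weights, the threshold and each library left out. Added after seeing the data were decoding without the groups, the most probable place for every cell, limma-voom on decoded reads and a fit without the 2 neutrophil libraries that stood apart.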

Results

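RNA was sequenced from neutrophils and macrophages sorted out of mammary tumours of mice in which E-cadherin and p53 are deleted in K14-expressing epithelium. The mice had received a control antibody, an antibody against CSF-1R (the receptor for the macrophage growth factors CSF-1 and IL-34), the DNA-crosslinking drug cisplatin with the control antibody, or cisplatin with anti-CSF-1R, called the combination here. Neutrophils gave 15 libraries: 4 control, 4 anti-CSF-1R, 3 cisplatin and 4 combination. Macrophages gave 12: 4 control, 2 anti-CSF-1R, 4 cisplatin and 2 combination. The table lists 9996 genes, over which the decoded reads came to 996270 to 3275638 per neutrophil library and 1295316 to 7475274 per macrophage library. Mice given cisplatin were killed 1 day after the second of 2 injections and the others when the tumour measured 100 mm2, so every comparison with and without cisplatin also compares these endpoints. Values are the authors' normalised read counts after the lost decimal points were decoded, n is the number of libraries with a decoded value, and fold changes are on the log2(value + 1) scale. Where a group had 1 decoded library, its spread was taken from the other groups of the cell type. For gene lists the median log2 fold change is given. The second p has the correlation between genes estimated, with left-out cells set to group means, so it may be too small. A list lost in some fits did not pass there with 1 library left out, and such fits kept the decoded places. Coordinates are GRCm38, the assembly of build mm10.

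The sorted populations carried their markers. Csf1r (chromosome 18, 61100598 to 61132149, plus strand) stood at 2195 ± 290.1 (SD, n = 4) in control macrophages and 1186 ± 130.4 (SD, n = 4) in control neutrophils (log2 fold change 0.88 ± 0.24 SE, adjusted p = 0.00323). In macrophages it stood at 1778 ± 516 (SD, n = 2) with anti-CSF-1R, 2353 ± 236 (SD, n = 4) with cisplatin and 1153 ± 38.4 (SD, n = 2) in the combination. Csf3r, the G-CSF receptor of neutrophils, stood at 6811 ± 1269.9 (SD, n = 4) in control neutrophils against 168 ± 92.3 (SD, n = 4) in control macrophages. All 21 measured neutrophil markers were lower in control macrophages (median log2 difference -5.45, adjusted p = 1.68e-16), and 27 of 28 macrophage markers were higher (median 2.58, adjusted p = 1.68e-10). With an estimated correlation these were adjusted p = 0.0454 and adjusted p = 0.0454. Of 9902 genes tested, 5044 differed between the control populations, 2600 higher in macrophages and 2444 higher in neutrophils. Ngp, a neutrophil granule protein, differed by -7.71 ± 0.71 (SE, adjusted p = 2.33e-08), and C6, a complement component, by 4.7 ± 0.71 (SE, adjusted p = 2.26e-05).

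**Figure D1:**
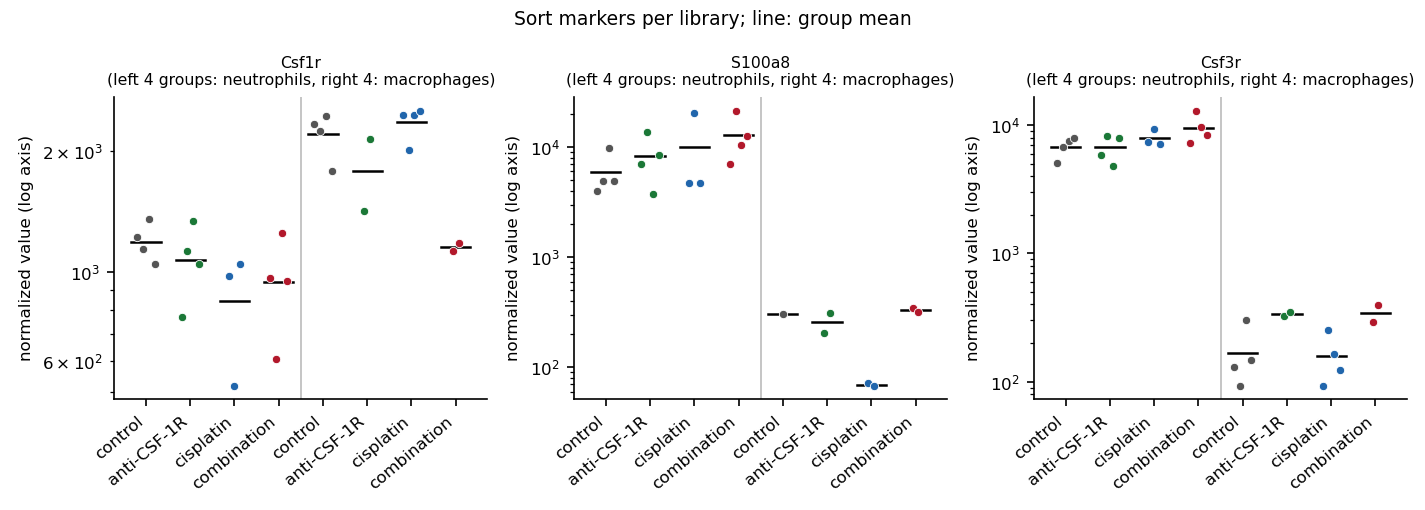
Normalised values (log axis) of Csf1r, S100a8 and Csf3r in each library with a decoded value, by cell type and treatment; points are libraries and lines are group means. S100a8 and Csf3r are higher in every neutrophil library shown than in any macrophage library shown.

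Anti-CSF-1R was compared with control to find what the macrophages left in the tumour express when their growth factor receptor is blocked. Ly6c2 and the eosinophil-associated ribonucleases Ear1 and Ear2 were higher, and cell cycle genes were lower. Ly6c2, a monocyte surface antigen (chromosome 15, 75108158 to 75111970, minus strand), stood at 122 ± 6.2 (SD, n = 2) with anti-CSF-1R and 2.58 ± 1.72 (SD, n = 4) in controls (log2 fold change 5.21 ± 0.54 SE, adjusted p = 0.000357). Ear2 (chromosome 14, 44102654 to 44103534, plus strand) stood at 40.7 ± 28.7 (SD, n = 2) against 1.03 ± 0.058 (SD, n = 4), and Ear1 at 35.2 ± 10.2 (SD, n = 2) against 1.03 ± 0.058 (SD, n = 4) (adjusted p = 0.00121 and 0.00108). Reads of Ear and Ly6 genes are uncertain because near-identical copies can share them. Rtn1, a reticulon of the endoplasmic reticulum (chromosome 12, 72211752 to 72409054, minus strand), was listed at 1, the lowest value in the table, in both anti-CSF-1R libraries and at 55.5 ± 29.7 (SD, n = 4) in controls (adjusted p = 0.000316). Chil3, a chitinase-like protein of alternatively activated macrophages, stood at 613 ± 215 (SD, n = 2) and 40.02 ± 7.68 (SD, n = 2) (adjusted p = 0.00931). Ly6c2, Ear2, Ear1 and Rtn1 also passed when decimal places were decoded without the groups, and Chil3 did not.

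Among proliferation genes, 31 of 33 members were lower (median -2.04, adjusted p = 4.89e-14, or 0.163 estimated). Of these 31, 10 passed over all genes and 24 over the list alone. Mcm6, a helicase subunit of DNA replication, stood at 2.13 ± 1.6 (SD, n = 2) with anti-CSF-1R and 73.7 ± 30.4 (SD, n = 3) in controls (adjusted p = 0.000462). The spindle checkpoint kinase Bub1b was listed at 1 in the only decoded anti-CSF-1R library and at 33.2 ± 9.16 (SD, n = 3) in controls, and the kinetochore genes Nuf2 and Casc5 and the histone gene Hist1h2bl were listed at 1 in each decoded anti-CSF-1R library (1 for Casc5 and for Hist1h2bl), against 35.3 ± 5.19 (SD, n = 2), 37.8 ± 25 (SD, n = 3) and 59.6 ± 23.1 (SD, n = 3) in controls. In the lysosome and lipid handling list, 28 of 32 members were higher (median 0.77, adjusted p = 4.93e-09, or 0.163 estimated). Of these 28, 8 passed over all genes and 18 over the list alone, and 0 and 3 passed the other way. Fabp5, a fatty acid binding protein, rose from 187 ± 48.7 (SD, n = 4) to 946 ± 101 (SD, n = 2), and the lysosomal protease Ctsd from 2815 ± 897 (SD, n = 4) to 9953 ± 402 (SD, n = 2) (adjusted p = 0.000432 and 0.00322). In the list of inflammatory cytokines and NF-kB targets, 32 of 34 members were higher (median 1.14, adjusted p = 3.69e-09, or 0.225 estimated). Of these 32, 4 passed over all genes and 16 over the list alone. Within the list of type I interferon-stimulated genes 42 of 55 members were higher (median 0.22, adjusted p = 0.0336, or 0.653 estimated). Of these 42, 3 passed over all genes and 3 over the list alone. The list did not pass with places decoded without the groups (adjusted p = 0.248), without control replicate 1 (0.169), without control replicate 2 (0.285), without control replicate 3 (0.313) and without anti-CSF-1R replicate 1 (0.726). Without anti-CSF-1R replicate 1 its direction turned. Among single genes, Ly6c2, Ear2, Ear1, Rtn1, Mcm6, Nuf2 and Fabp5 passed without any 1 library. Chil3 and Ctsd did not pass without anti-CSF-1R replicate 2 (adjusted p = 0.0761 and 0.0524), nor did Casc5 without control replicate 1 (adjusted p = 0.0604). Bub1b, Hist1h2bl and Casc5 could not be fitted without the only decoded anti-CSF-1R library, and Bub1b and Hist1h2bl passed in the other fits.

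Markers of other cell types moved with this comparison. Of the neutrophil markers, 13 of 17 members were higher (median 1.2, adjusted p = 0.00153, or 0.282 estimated). Of these 13, 1 passed over all genes and 9 over the list alone. Eosinophil markers, which include Ear1 and Ear2, were higher in 3 of 3 members (median 4.13, adjusted p = 0.00153, or 0.145 estimated). Mast cell markers passed too, with 4 of 4 higher (median 4.15, adjusted p = 0.00053, or 0.145 estimated), but they were high in replicate 2 of the anti-CSF-1R macrophages (mean log2 deviation 5.89) and not in replicate 1 (-1.35). The mast cell tryptase Tpsab1 and the IL-33 receptor Il1rl1, at 4467 and 319, were decoded in 1 of these 2 libraries. The list of immediate early and heat shock genes (16 of 25 higher, median 0.19, adjusted p = 0.0438, or 0.631 estimated, lost in 3 of 6 fits, at up to 0.391 without control replicate 1) also passed. In all, 303 of 9086 genes passed, 134 higher and 169 lower. Without replicate 2 of the anti-CSF-1R macrophages 38 passed, without control replicate 4 there were 564, and 95 passed when places were decoded without the groups.

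Cisplatin was compared with control to find the response of macrophages to the drug. In macrophages given cisplatin with the control antibody, p53 target genes were higher. Of the p53 and DNA damage response list, 22 of 24 members were higher (median 0.41, adjusted p = 7.04e-09, or 0.00426 estimated). Of these 22, 4 passed over all genes and 7 over the list alone. Ccng1, cyclin G1 (chromosome 11, 40748552 to 40755311, minus strand), rose from 255 ± 22.5 (SD, n = 4) to 687 ± 36.1 (SD, n = 4) (log2 fold change 1.43 ± 0.15 SE, adjusted p = 0.000349). Zmat3, a zinc finger gene induced by p53, rose from 36.4 ± 10.3 (SD, n = 4) to 137 ± 38.4 (SD, n = 4), and Trp53inp1 by 1.51 on the log2 scale (adjusted p = 0.00697 and 0.0117). The chemokine Ccl9 stood at 2318 ± 584 (SD, n = 3) with cisplatin and 508 ± 158 (SD, n = 4) in controls (log2 fold change 2.22 ± 0.32 SE, adjusted p = 0.00604). Ccng1 and Ccl9 were the genes named here that passed with places decoded without the groups.

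Other genes rose with cisplatin in the decoding that uses the groups, among them the hyaluronan receptor Lyve1, the lipoxygenase Alox5 and the glucocorticoid-induced gene Fkbp5 (log2 fold changes 2.86, 3.03 and 2.73). The gelatinase Mmp9, the calgranulin S100a8 and Ifitm1 fell (log2 fold changes -3.45, -2.11 and -2.78). None of these 6 passed with places decoded without the groups (log2 fold changes 3.24, 0.79, 1.78, -1.82, -2.11 and -0.82 in this order). The transcription factor Etv1 was listed at 177 ± 18.1 (SD, n = 4) with cisplatin and 9.5 ± 5.12 (SD, n = 4) in controls, and the collagenase Mmp13 at 30.1 ± 5.33 (SD, n = 3) and 717 ± 426 (SD, n = 2) (adjusted p = 6.32e-06 and 0.000266). Neither could be tested with places decoded without the groups, and for Ep400, a chromatin remodeller with a log2 fold change of 2.98 ± 0.2 SE, that decoding turned the direction to -0.29. Of the macrophage markers, 21 of 28 members were higher (median 0.2, adjusted p = 0.0163, or 0.341 estimated). Of these 21, 1 passed over all genes and 3 over the list alone. The list did not pass after quantile normalisation (adjusted p = 0.0989), without cisplatin replicate 3 (0.0816) and without control replicate 1 (0.0722). Of the complement genes, 13 of 15 members were higher (median 0.4, adjusted p = 0.00342, or 0.244 estimated). Of these 13, limma passed 0 over all genes and 1 over the list alone, with 4 at an unadjusted p under 0.05. Lower were mast cell and basophil markers (4 of 4 lower, median -2.04, adjusted p = 0.00342, or 0.244 estimated, lost in 1 of 7 fits, at up to 0.0574 without cisplatin replicate 1). In all, 43 of 9203 genes passed, 25 higher and 18 lower, and 2 with places decoded without the groups. The count was 17 without cisplatin replicate 3 and 133 without cisplatin replicate 2. Among single genes, Ccng1, Zmat3, Ccl9, Etv1 and Mmp13 passed without any 1 library. Alox5 and Fkbp5 did not pass without cisplatin replicate 3 (adjusted p = 0.132 and 0.0864), nor did Mmp9 without control replicate 3 (adjusted p = 0.0532), nor did Trp53inp1 without cisplatin replicate 4 (adjusted p = 0.0576). Lyve1, S100a8 and Ifitm1 did not pass in 4 of 8, 3 of 7 and 3 of 7 fits without 1 library (adjusted p up to 0.119, 0.217 and 0.213, each without cisplatin replicate 3). S100a8 and Ifitm1 could not be fitted without the only decoded control library.

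Whether anti-CSF-1R alters macrophages of cisplatin-treated tumours was tested by comparing the combination with cisplatin. The chemokine receptor Cx3cr1 (chromosome 9, 119901616 to 120069879, minus strand) was lower in the combination, at 55.5 ± 36.3 (SD, n = 2) against 796 ± 75.9 (SD, n = 4) with cisplatin (log2 fold change -3.98 ± 0.38 SE, adjusted p = 0.000121). Ly6c2 was higher, at 398 ± 338 (SD, n = 2) against 8.73 ± 3.36 (SD, n = 3) (log2 fold change 5.1 ± 0.57 SE, adjusted p = 0.00104). Plet1, a surface antigen of epithelial progenitors and some myeloid cells, and Ear2 were among the largest rises. In the only decoded combination library Plet1 stood at 169 and Ear2 at 109, and both were listed at 1 in each decoded cisplatin library (adjusted p = 0.0161 and 0.00139, with the spread of the combination group taken from the other groups). Rtn1 stood at 1.44 ± 0.616 (SD, n = 2) and 34.4 ± 9.3 (SD, n = 3) (adjusted p = 0.00199), and the organic anion transporter Slco2b1 at 9.04 ± 5.75 (SD, n = 2) and 141 ± 44.2 (SD, n = 4) (adjusted p = 0.00205). Csf1r itself stood at 1153 ± 38.4 (SD, n = 2) and 2353 ± 236 (SD, n = 4) (log2 fold change -1.02 ± 0.24 SE, adjusted p = 0.029). These genes except Ly6c2, which could not be tested, also passed with places decoded without the groups. Of the macrophage markers, 18 of 27 members were lower (median -0.37, adjusted p = 0.000674, or 0.0489 estimated). Of these 18, 6 passed over all genes and 9 over the list alone, and 0 and 1 passed the other way. Among them C1qc, a complement C1q chain, stood at 1013 ± 287 (SD, n = 2) in the combination and 3165 ± 603 (SD, n = 4) with cisplatin (adjusted p = 0.00479).

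**Figure D2:**
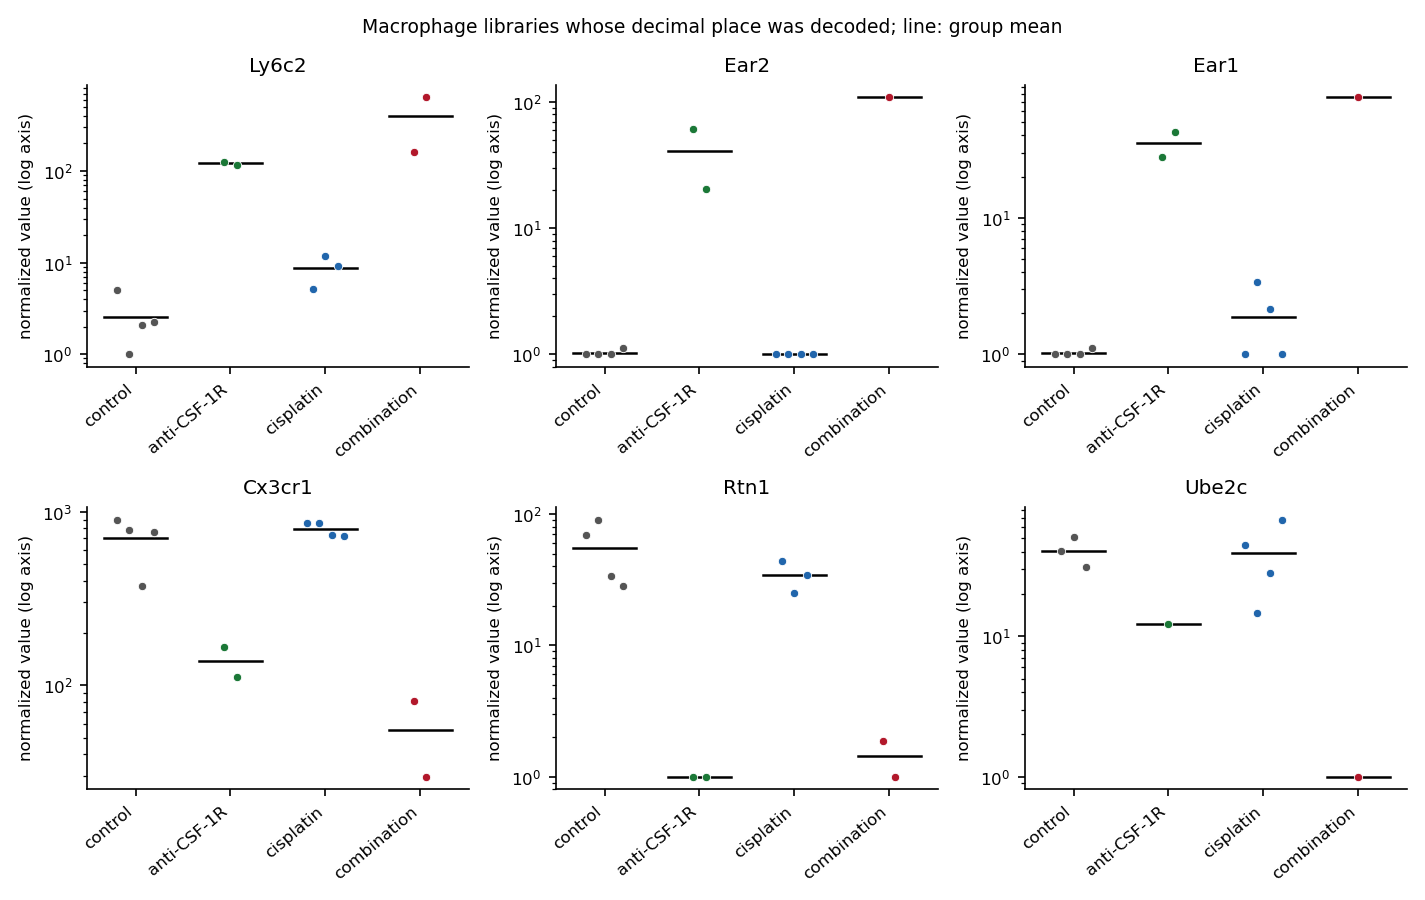
Normalised values (log axis) of 6 genes in the macrophage libraries whose decimal place was decoded, by treatment; points are libraries and lines are group means. Ly6c2, Ear2 and Ear1 are higher and Cx3cr1, Rtn1 and Ube2c lower in each decoded anti-CSF-1R and combination library than in each decoded library without the antibody.

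Interferon-responsive genes were higher in the combination. Of type I interferon-stimulated genes, 54 of 56 members were higher (median 1.41, adjusted p = 1.27e-19, or 0.114 estimated). Of these 54, 11 passed over all genes and 38 over the list alone. The antiviral gene Rsad2 (chromosome 12, 26442746 to 26456452, minus strand) stood at 1641 ± 344 (SD, n = 2) and 219 ± 34.2 (SD, n = 3) (log2 fold change 2.9 ± 0.39 SE, adjusted p = 0.00246). Of the interferon-gamma-responsive genes, 26 of 29 members were higher (median 1.5, adjusted p = 1.31e-09, or 0.114 estimated). Of these 26, 3 passed over all genes and 19 over the list alone, and 0 and 1 passed the other way. Of the chemokines that attract T cells and costimulatory genes, 13 of 15 members were higher (median 1.93, adjusted p = 5.12e-08, or 0.0727 estimated). Of these 13, 6 passed over all genes and 9 over the list alone. Ccl5 stood at 250.4 ± 192 (SD, n = 2) and 18.3 ± 5.85 (SD, n = 3) (adjusted p = 0.00573). Of the proliferation genes, 29 of 32 members were lower (median -1.62, adjusted p = 1.32e-11, or 0.114 estimated). Of these 29, 11 passed over all genes and 21 over the list alone, and 0 and 2 passed the other way. The ubiquitin-conjugating enzyme Ube2c was listed at 1 in the only decoded combination library and at 39 ± 23 (SD, n = 4) with cisplatin (adjusted p = 0.00779, with the spread likewise taken from the other groups). Of lysosome and lipid handling genes, 24 of 32 members were higher (median 0.43, adjusted p = 3.05e-06, or 0.114 estimated). Of these 24, 8 passed over all genes and 11 over the list alone. Fabp5 stood at 847 ± 152 (SD, n = 2) and 84.6 ± 14.9 (SD, n = 4) (adjusted p = 1.69e-05).

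Neutrophil and eosinophil markers moved with these lists. Of the neutrophil markers, 17 of 18 members were higher (median 1.68, adjusted p = 1.21e-08, or 0.0344 estimated). Of these 17, 6 passed over all genes and 9 over the list alone. S100a8 stood at 333 ± 22.9 (SD, n = 2) and 69.9 ± 2.31 (SD, n = 2) (adjusted p = 0.00452). Of the eosinophil markers, 3 of 3 members were higher (median 4.82, adjusted p = 1.48e-05, or 0.0236 estimated). Of these 3, 2 passed over all genes and 3 over the list alone. Others that passed included monocyte markers (11 of 16 higher, median 0.97, adjusted p = 0.00141, or 0.0613 estimated) and fibroblast markers (10 of 11 higher, median 0.77, adjusted p = 0.0193, or 0.145 estimated, lost in 1 of 6 fits, at up to 0.289 without combination replicate 1). In all, 352 of 9083 genes passed, 155 higher and 197 lower, and 147 with places decoded without the groups. Without combination replicate 2 the count was 16, without cisplatin replicate 2 it was 541, and with the 2 groups alone in the fit it was 609. Among single genes, Cx3cr1, Ly6c2 and Rtn1 passed without any 1 library. Rsad2 and Slco2b1 did not pass without combination replicate 2 (adjusted p = 0.0566 and 0.0566). Csf1r did not pass in 5 of 6 fits without 1 library (adjusted p up to 0.206 without combination replicate 1). Plet1, Ear2 and Ube2c could not be fitted without the only decoded combination library, and passed in the other fits.

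With anti-CSF-1R in both arms, adding cisplatin passed the threshold for no single macrophage gene. limma called 0 of 8977 genes, with 787 at an unadjusted p under 0.05, and limma-voom on the decoded reads called 5. As a list, 53 of 55 type I interferon-stimulated genes were higher (median 1.2, adjusted p = 7.32e-22, or 0.155 estimated). Of these 53, limma passed 0 over all genes and 17 over the list alone, with 30 at an unadjusted p under 0.05. Markers passed with it: macrophage markers (18 of 26 lower, median -0.38, adjusted p = 0.0477, or 0.272 estimated, lost in 2 of 4 fits, at up to 0.455 without anti-CSF-1R replicate 1), dendritic cell markers (8 of 10 lower, median -0.88, adjusted p = 0.0474, or 0.247 estimated, lost in 4 of 4 fits, at up to 0.607 without anti-CSF-1R replicate 2), eosinophil markers (3 of 3 higher, median 1.28, adjusted p = 0.0474, or 0.15 estimated, lost in 1 of 2 fits, at up to 0.0551 without anti-CSF-1R replicate 2), fibroblast markers (8 of 10 higher, median 0.82, adjusted p = 0.0286, or 0.155 estimated, lost in 3 of 4 fits, at up to 0.7 without anti-CSF-1R replicate 2), mast cell and basophil markers (3 of 3 lower, median -5.19, adjusted p = 0.00113, or 0.0468 estimated), which were high in anti-CSF-1R replicate 2, and monocyte markers (12 of 15 higher, median 0.82, adjusted p = 0.000106, or 0.0468 estimated), and so did immediate early and heat shock genes (20 of 25 higher, median 0.29, adjusted p = 0.025, or 0.659 estimated, lost in 2 of 4 fits, at up to 0.157 without anti-CSF-1R replicate 1). In the p53 and DNA damage response list, 16 of 24 members were higher (median 0.49, adjusted p = 0.00113, or 0.0468 estimated). Of these 16, limma passed 0 over all genes and 3 over the list alone, with 7 at an unadjusted p under 0.05. Against control, the combination changed 290 of 9082 genes, 133 higher and 157 lower, with 98 when places were decoded without the groups, 22 without combination replicate 2 and 606 without control replicate 4. There, 55 of 56 type I interferon-stimulated genes were higher (median 1.56, adjusted p = 1.55e-23, or 0.106 estimated). Of these 55, 14 passed over all genes and 36 over the list alone. Of the p53 list, 20 of 24 members were higher (median 0.52, adjusted p = 0.000148, or 0.0331 estimated). Of these 20, 4 passed over all genes and 8 over the list alone, and 0 and 1 passed the other way. Other lists that passed against control included eosinophil markers (3 of 3 higher, median 5.25, adjusted p = 2.35e-05, or 0.0273 estimated), neutrophil markers (15 of 18 higher, median 1.11, adjusted p = 0.000209, or 0.103 estimated), monocyte markers (12 of 16 higher, median 0.73, adjusted p = 0.000128, or 0.0567 estimated) and immediate early and heat shock genes (20 of 25 higher, median 0.69, adjusted p = 1.69e-05, or 0.315 estimated). Mdm2, the p53 ubiquitin ligase, stood at 1683 ± 477 (SD, n = 2) in the combination and 674 ± 214 (SD, n = 4) in controls (log2 fold change 1.36 ± 0.3 SE, adjusted p = 0.0244). The interaction, which tests whether cisplatin altered the effect of anti-CSF-1R, called Etv1 and Ep400 (log2 fold change -2.83, turned to 0.44 with places decoded without the groups). Mdm2 did not pass in 3 of 6 fits without 1 library (adjusted p up to 0.346 without combination replicate 2). In the interaction Etv1, on places decoded with the groups, passed without any 1 library. Ep400 did not pass without combination replicate 2. With places decoded without the groups limma called 0 in the interaction, with 631 genes at an unadjusted p under 0.05, and limma-voom called 6. In the interaction 46 of 55 type I interferon-stimulated genes were higher (median 0.95, adjusted p = 3.31e-09, or 0.302 estimated). Of these 46, limma passed 0 over all genes and 2 over the list alone, with 10 at an unadjusted p under 0.05. Markers that passed there were neutrophil markers (11 of 17 higher, median 0.62, adjusted p = 0.0388, or 0.26 estimated, lost in 6 of 12 fits, at up to 0.513 without anti-CSF-1R replicate 1), monocyte markers (12 of 15 higher, median 0.34, adjusted p = 0.0182, or 0.181 estimated, lost in 3 of 12 fits, at up to 0.164 without control replicate 4), fibroblast markers (9 of 10 higher, median 0.81, adjusted p = 0.0182, or 0.181 estimated, lost in 3 of 12 fits, at up to 0.156 without anti-CSF-1R replicate 2) and macrophage markers (20 of 26 lower, median -0.56, adjusted p = 0.0029, or 0.181 estimated, lost in 1 of 12 fits, at up to 0.0928 without anti-CSF-1R replicate 1).

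In neutrophils, anti-CSF-1R was compared with control to find whether they differ when the macrophage growth factor receptor is blocked. Inflammatory, interferon and dendritic cell lists were higher and proliferation genes lower, while few single genes passed. Of inflammatory cytokines and NF-kB targets, 34 of 36 members were higher (median 0.74, adjusted p = 2.27e-13, or 0.119 estimated). Of these 34, limma passed 0 over all genes and 13 over the list alone, with 18 at an unadjusted p under 0.05. Of type I interferon-stimulated genes, 50 of 57 members were higher (median 0.79, adjusted p = 1.52e-11, or 0.211 estimated). Of these 50, limma passed 0 over all genes and 7 over the list alone, with 17 at an unadjusted p under 0.05. Of dendritic cell markers, 10 of 12 members were higher (median 0.36, adjusted p = 0.000238, or 0.0175 estimated). Of these 10, limma passed 0 over all genes and 5 over the list alone, with 5 at an unadjusted p under 0.05. Of proliferation genes, 20 of 26 members were lower (median -1.02, adjusted p = 6.28e-06, or 0.0175 estimated). Of these 20, limma passed 0 over all genes and 3 over the list alone, with 10 at an unadjusted p under 0.05. The interferon-inducible GTPase Irgm2 (chromosome 11, 58199618 to 58222782, plus strand) stood at 386 ± 64.6 (SD, n = 4) with anti-CSF-1R and 80.2 ± 22.9 (SD, n = 4) in controls (log2 fold change 2.28 ± 0.24 SE, adjusted p = 0.000146). Ctsk, a cysteine protease of osteoclasts, stood at 7.14 ± 0.612 (SD, n = 3) and 251 ± 232 (SD, n = 3) (log2 fold change -4.5 ± 0.6 SE, adjusted p = 0.0227).

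Macrophage and B cell markers moved with these lists. Of the macrophage markers, 23 of 27 members were lower (median -0.36, adjusted p = 6.28e-06, or 0.211 estimated). Of these 23, limma passed 0 over all genes and 7 over the list alone, with 10 at an unadjusted p under 0.05, and 0 and 1 passed the other way. C1qa stood at 21 ± 8.81 (SD, n = 4) with anti-CSF-1R and 91.3 ± 39.6 (SD, n = 4) in controls (adjusted p = 0.0928). Of the B cell and plasma cell markers, 10 of 10 members were higher (median 2.3, adjusted p = 6.28e-06, or 0.126 estimated). Of these 10, limma passed 0 over all genes and 4 over the list alone, with 5 at an unadjusted p under 0.05. The list did not pass with the most probable place used for every cell (adjusted p = 0.147) and without anti-CSF-1R replicate 1 (0.759). Their level was highest in replicate 1 of the anti-CSF-1R neutrophils (mean log2 deviation 2.98). Lists that also passed included monocyte markers (11 of 17 higher, median 0.23, adjusted p = 0.0337, or 0.163 estimated, lost in 4 of 8 fits, at up to 0.171 without control replicate 3) and mammary tumour and epithelial cell markers (8 of 10 lower, median -0.8, adjusted p = 0.00738, or 0.163 estimated, lost in 1 of 8 fits, at up to 0.216 without control replicate 3). Irgm2 and Ctsk were the genes of 9124 to pass, with 832 at an unadjusted p under 0.05, and 11 passed without control replicate 4. With places decoded without the groups limma called 0 genes, with 670 at an unadjusted p under 0.05. On places decoded with the groups limma-voom called 3. Among single genes, Irgm2 passed without any 1 library. Ctsk did not pass in 4 of 8 fits without 1 library (adjusted p up to 0.0871 without control replicate 2).

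Cisplatin with the control antibody was compared with control for the response of neutrophils to the drug. It changed 6 of 9109 genes, 5 higher and 1 lower. Irgm2 stood at 315 ± 98 (SD, n = 3) against 80.2 ± 22.9 (SD, n = 4) (log2 fold change 1.96 ± 0.26 SE, adjusted p = 0.00147). Klhl6, a ubiquitin ligase adaptor, stood at 1033 ± 297 (SD, n = 2) and 103 ± 47.3 (SD, n = 4), and Sgms1, a sphingomyelin synthase, at 403 ± 177 (SD, n = 2) and 46.5 ± 14.7 (SD, n = 4) (adjusted p = 0.00106 for both). Ptpn22, a lymphoid phosphatase, and Nars2, a mitochondrial tRNA synthetase, rose by 3.18 and 2.54 on the log2 scale. The antimicrobial peptide gene Camp, decoded in 1 control library, was listed at 1 in both decoded cisplatin libraries. Higher as a list were type I interferon-stimulated genes (42 of 57 higher, median 0.53, adjusted p = 6.22e-05, or 0.615 estimated, lost in 1 of 7 fits, at up to 0.0597 without cisplatin replicate 1). Of ribosomal protein genes, 79 of 80 members were lower (median -0.43, adjusted p = 3.08e-13, or 0.615 estimated). Of these 79, limma passed 0 over all genes and 0 over the list alone, with 8 at an unadjusted p under 0.05. Of neutrophil markers, 21 of 21 members were higher (median 0.52, adjusted p = 8.43e-05, or 0.615 estimated). Of these 21, limma passed 0 over all genes and 1 over the list alone, with 2 at an unadjusted p under 0.05. The list did not pass after quantile normalisation (adjusted p = 0.0827), without the pair of neutrophil libraries that stood apart (0.722) and without cisplatin replicate 2 (0.912). Also lower as a list were mammary tumour and epithelial cell markers (9 of 10 lower, median -1.06, adjusted p = 0.000109, or 0.188 estimated). With places decoded without the groups limma called 0 genes, with 598 at an unadjusted p under 0.05. On places decoded with the groups limma-voom called 5. Without cisplatin replicate 2 there was 1 call. Among single genes, Irgm2 passed without any 1 library. Klhl6 and Sgms1 did not pass without cisplatin replicate 2 (adjusted p = 0.0708 and 0.0708). Ptpn22, Nars2 and Camp did not pass in 2 of 7, 2 of 7 and 3 of 6 fits without 1 library (adjusted p up to 0.124, 0.11 and 0.106, each without cisplatin replicate 3). Camp could not be fitted without the only decoded control library.

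Neutrophils of the combination were compared with those of cisplatin alone. Interferon-responsive genes were higher in the combination. Of type I interferon-stimulated genes, 57 of 57 members were higher (median 1.17, adjusted p = 1.64e-29, or 0.074 estimated). Of these 57, 1 passed over all genes and 25 over the list alone. Of interferon-gamma-responsive genes, 28 of 31 members were higher (median 1.36, adjusted p = 8.04e-18, or 0.0391 estimated). Of these 28, 2 passed over all genes and 15 over the list alone. The guanylate-binding protein Gbp4 stood at 274 ± 151 (SD, n = 3) in the combination and 19.3 ± 1.31 (SD, n = 3) with cisplatin (log2 fold change 3.55 ± 0.45 SE, adjusted p = 0.0159). The T cell chemokine Cxcl9 stood at 241 ± 108 (SD, n = 3) and 43.4 ± 12.5 (SD, n = 3) (log2 fold change 2.38 ± 0.39 SE, adjusted p = 0.0315). Usp18, an inhibitor of interferon receptor signalling, stood at 392 ± 166 (SD, n = 4) and 20.9 (n = 1) (adjusted p = 0.0298, with the spread of the cisplatin group taken from the other groups). Ctsk and the myelin protein gene Pmp22 fell (log2 fold changes -5.99 and -3.68). Of monocyte markers, 14 of 17 members were higher (median 0.57, adjusted p = 0.000401, or 0.0391 estimated). Of these 14, limma passed 0 over all genes and 3 over the list alone, with 5 at an unadjusted p under 0.05. Of dendritic cell markers, 11 of 12 members were higher (median 0.39, adjusted p = 0.0024, or 0.0391 estimated). Of these 11, limma passed 0 over all genes and 1 over the list alone, with 3 at an unadjusted p under 0.05. Further markers passed: eosinophil markers (5 of 6 higher, median 1.77, adjusted p = 0.00221, or 0.177 estimated, lost in 2 of 7 fits, at up to 0.0956 without cisplatin replicate 3), macrophage markers (16 of 27 lower, median -0.3, adjusted p = 0.00692, or 0.424 estimated, lost in 3 of 7 fits, at up to 0.49 without cisplatin replicate 3) and mammary tumour and epithelial cell markers (9 of 10 higher, median 0.78, adjusted p = 0.0333, or 0.307 estimated, lost in 4 of 7 fits, at up to 0.3 without combination replicate 1). In all, 9 of 9106 genes passed, 5 higher and 4 lower, and 4 without cisplatin replicate 1. With places decoded without the groups limma called 0, with 672 at an unadjusted p under 0.05. On places decoded with the groups limma-voom called 5. Among single genes, Gbp4 passed without any 1 library. Ctsk did not pass without combination replicate 2 (adjusted p = 0.0911), nor did Usp18 without combination replicate 1 (adjusted p = 0.0549). Cxcl9 did not pass in 5 of 7 fits without 1 library (adjusted p up to 0.126 without combination replicate 4). Pmp22, Ctsk and Usp18 could not be fitted without the only decoded cisplatin library, and Pmp22 passed in the other fits.

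The interferon lists were highest in the combination. Mean log2 deviations of type I interferon-stimulated genes were -1.12 ± 0.8 (SD, n = 4) in control, -0.2 ± 0.78 (SD, n = 4) with anti-CSF-1R, -0.3 ± 0.35 (SD, n = 3) with cisplatin and 0.96 ± 0.35 (SD, n = 4) in the combination. Against control, 57 of 57 members were higher (median 1.8, adjusted p = 1.31e-35, or 0.0423 estimated). Of these 57, 20 passed over all genes and 48 over the list alone. Rsad2 stood at 6709 ± 4283 (SD, n = 4) in the combination and 638 ± 711 (SD, n = 4) in controls (log2 fold change 4.09 ± 0.68 SE, adjusted p = 0.0111), and it also passed with places decoded without the groups. Isg15, a ubiquitin-like protein (chromosome 4, 156199424 to 156200818, minus strand), stood at 1258 ± 495 (SD, n = 4) and 85.8 ± 6.19 (SD, n = 2) (log2 fold change 3.77 ± 0.54 SE, adjusted p = 0.00461). The antiviral genes Ifit1 and Oas1g rose by 3.35 and 3.47 on the log2 scale. Of interferon-gamma-responsive genes, 29 of 31 members were higher (median 1.71, adjusted p = 6.03e-15, or 0.0423 estimated). Of these 29, 5 passed over all genes and 18 over the list alone, and 0 and 1 passed the other way. Of MHC class I presentation genes, 15 of 18 members were higher (median 0.87, adjusted p = 1.51e-05, or 0.194 estimated). Of these 15, 5 passed over all genes and 9 over the list alone, and 0 and 2 passed the other way. The peptide transporter Tap1 stood at 209 ± 119 (SD, n = 3) and 45.6 ± 10.7 (SD, n = 3) (adjusted p = 0.0306). Of proliferation genes, 22 of 26 members were lower (median -0.63, adjusted p = 0.000224, or 0.0423 estimated). Of these 22, limma passed 0 over all genes and 3 over the list alone, with 6 at an unadjusted p under 0.05, and 0 and 1 passed the other way. Markers that passed as lists were neutrophil markers (20 of 21 higher, median 0.72, adjusted p = 4.41e-05, or 0.568 estimated), eosinophil markers (5 of 6 higher, median 1.64, adjusted p = 0.0023, or 0.182 estimated), monocyte markers (12 of 17 higher, median 0.68, adjusted p = 0.00882, or 0.103 estimated, lost in 1 of 8 fits, at up to 0.057 without combination replicate 1) and dendritic cell markers (9 of 12 higher, median 0.36, adjusted p = 0.0472, or 0.127 estimated, lost in 4 of 8 fits, at up to 0.142 without combination replicate 1).

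The combination changed 98 of 9123 genes against control, 79 higher and 19 lower, and 3 with places decoded without the groups. Without combination replicate 2 the count was 7, and without control replicate 4 it was 163. Ifit1 did not pass without combination replicate 2 (adjusted p = 0.0595). Isg15, Rsad2 and Oas1g did not pass in 2 of 8, 2 of 8 and 2 of 8 fits without 1 library (adjusted p up to 0.0615 without control replicate 3, 0.0595 without combination replicate 2 and 0.0683 without control replicate 1). Ifit1 could not be fitted without the only decoded control library. Against anti-CSF-1R, 2 of 9121 genes passed, the guanylate-binding protein gene Gbp10 (log2 fold change 4.1 ± 0.46 SE, adjusted p = 0.00641) and the polarity gene Mpp7 (log2 fold change -2.81 ± 0.45 SE, adjusted p = 0.04). With places decoded without the groups limma called 0, with 758 at an unadjusted p under 0.05. On places decoded with the groups limma-voom called 2. In that comparison 56 of 57 type I interferon-stimulated genes were higher (median 1.11, adjusted p = 1.09e-21, or 0.3 estimated). Of these 56, limma passed 0 over all genes and 24 over the list alone, with 35 at an unadjusted p under 0.05. Other lists that passed included neutrophil markers (19 of 21 higher, median 0.51, adjusted p = 0.00502, or 0.648 estimated, lost in 2 of 8 fits, at up to 0.534 without combination replicate 2), B cell and plasma cell markers (8 of 9 lower, median -1.42, adjusted p = 0.00502, or 0.393 estimated, lost in 2 of 8 fits, at up to 0.792 without anti-CSF-1R replicate 1), fibroblast markers (14 of 16 higher, median 0.72, adjusted p = 0.0104, or 0.393 estimated, lost in 1 of 8 fits, at up to 0.124 without combination replicate 4), mast cell and basophil markers (5 of 6 lower, median -1.33, adjusted p = 0.0425, or 0.393 estimated, lost in 3 of 8 fits, at up to 0.927 without anti-CSF-1R replicate 3) and immediate early and heat shock genes (20 of 25 higher, median 0.37, adjusted p = 0.00502, or 0.393 estimated, lost in 1 of 8 fits, at up to 0.136 without combination replicate 2). The interaction called 1 gene, Pmp22 (adjusted p = 0.0192), with 519 at an unadjusted p under 0.05, and 6 lists: mammary tumour and epithelial cell markers (8 of 10 higher, median 1.71, adjusted p = 0.000352, or 0.188 estimated), inflammatory cytokines and NF-kB targets (29 of 36 lower, median -0.48, adjusted p = 0.000549, or 0.778 estimated), type I interferon-stimulated genes (42 of 57 higher, median 0.44, adjusted p = 0.00209, or 0.83 estimated, lost in 4 of 15 fits, at up to 0.566 without control replicate 4), interferon-gamma-responsive genes (24 of 31 higher, median 0.71, adjusted p = 0.000254, or 0.536 estimated, lost in 1 of 15 fits, at up to 0.709 without control replicate 4), oxidative phosphorylation (55 of 73 higher, median 0.17, adjusted p = 0.00793, or 0.882 estimated, lost in 4 of 15 fits, at up to 0.307 without combination replicate 4) and glycolysis and hypoxia (28 of 35 lower, median -0.38, adjusted p = 0.0207, or 0.882 estimated, lost in 7 of 15 fits, at up to 0.589 without cisplatin replicate 2). The highest p of the interferon and glycolysis lists came with a turned direction. Gbp10 did not pass without combination replicate 4 (adjusted p = 0.125). Mpp7 did not pass in 7 of 8 fits without 1 library (adjusted p up to 0.293 without anti-CSF-1R replicate 3). Pmp22 did not pass in 3 of 14 fits without 1 library (adjusted p up to 0.0825 without combination replicate 4). Pmp22 could not be fitted without the only decoded cisplatin library.

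**Figure D3:**
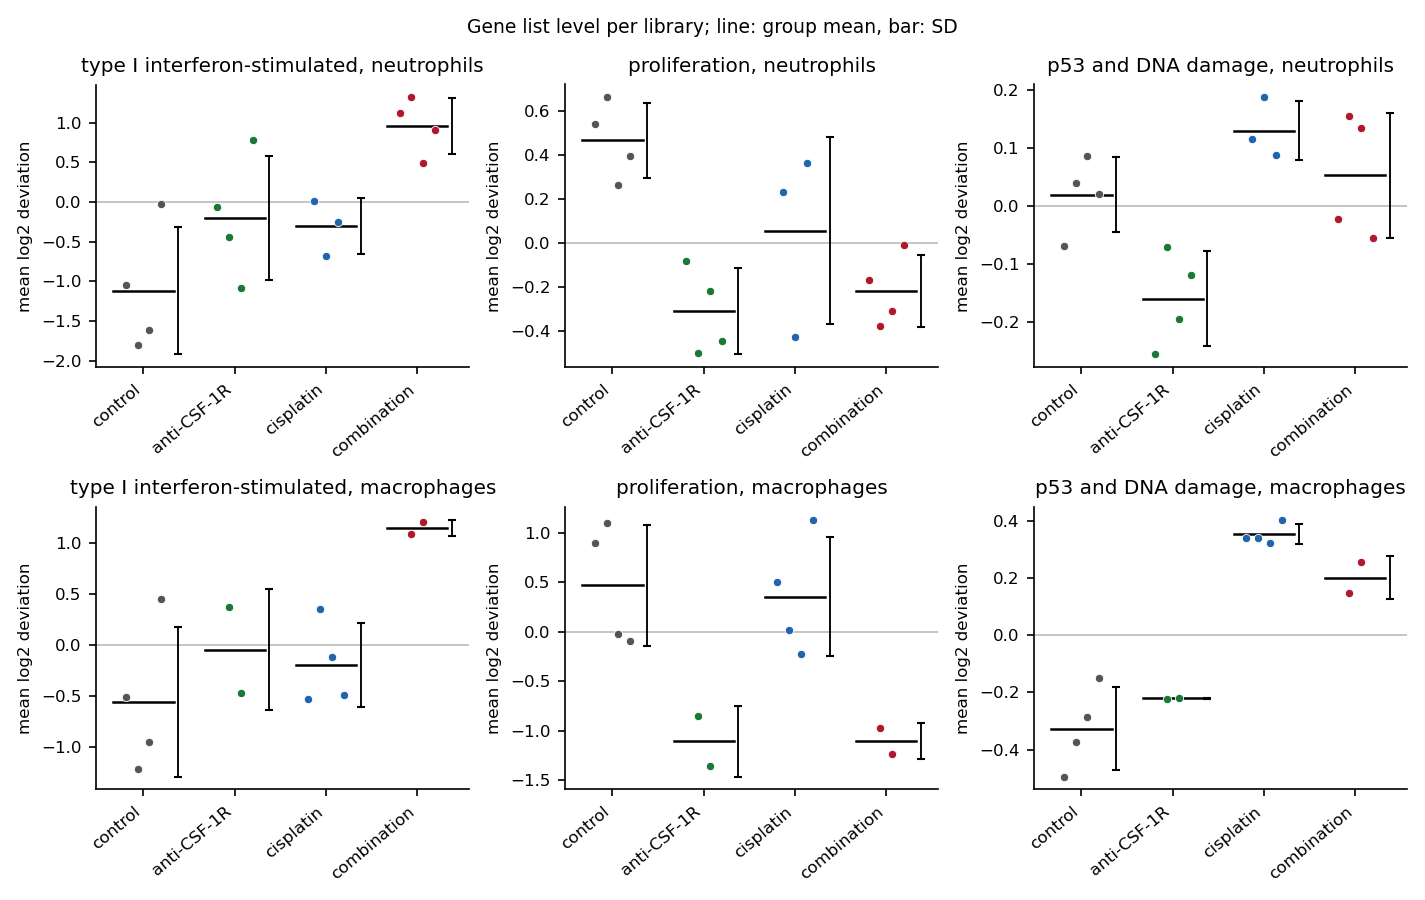
Mean log2 deviation of 3 gene lists from their mean over the libraries of the cell type, by treatment; points are libraries, lines group means and bars the SD. The group mean of type I interferon-stimulated genes is highest in the combination in both cell types, and proliferation genes are lower in the 4 macrophage libraries with anti-CSF-1R than in the 8 without.

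The responses of the populations were compared with each other. For the combination against control, 15 genes were higher in both cell types where 1.14 were expected from independent lists, and 3 were lower in both where 0.263 were expected. Rsad2, Ddx58, Oasl2 and Parp14, genes of the interferon response, were among those shared. With places decoded without the groups 1 gene was shared, and with limma-voom 0. The effect of adding anti-CSF-1R to cisplatin differed between macrophages and neutrophils for 16 genes, that of anti-CSF-1R for 18 and that of cisplatin for 9. For anti-CSF-1R these included the mast cell protease genes Mcpt4 and Cma1. In treated macrophages both rest on 1 decoded library, replicate 2 with high mast cell markers, so these calls are no measure of the treatment. The p53 and DNA damage response list rose more with cisplatin in macrophages (median log2 difference 0.55, adjusted p = 0.00127, or 0.0281 estimated).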

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

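The tests of 1 combination library that stands apart, of macrophage RNA, of a lower share of macrophages, of depth and of tumour cell RNA, and the splits of the neutrophil libraries and of macrophages with cisplatin, were chosen only after the results were seen. In 7 of 169 groups of 4 libraries, 1 library stood far from the others, where chance gives 8.45. Macrophage cisplatin replicate 2 had Csf1r at 2002 (the others 2449.7 to 2508) and ribosomal protein genes at a mean log2 deviation of -0.346 (the others 0.0902 to 0.122). Interferon-gamma-responsive genes stood at 0.553 (the others -0.794 to -0.624) in macrophage control replicate 4 and at 0.251 (the others -1.3 to -1.1) in neutrophil control replicate 4. Dendritic cell markers stood at -0.0128 (the others 0.556 to 0.628) in neutrophil anti-CSF-1R replicate 2. In neutrophil control replicate 3, S100a8 stood at 9738 (the others 4006 to 4884) and B cell and plasma cell markers at 1.27 (the others -1.22 to -0.89).

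Tests of a difference between effects gave further results. Between macrophages and neutrophils, the effect of adding anti-CSF-1R to cisplatin differed for 16 genes (0 to 44 without 1 library, lowest without macrophage combination replicate 1), that of anti-CSF-1R for 18 (2 to 43) and that of cisplatin for 9 (3 to 17). The interaction of the drugs called 1 gene in neutrophils and 2 in macrophages. Mast cell and basophil markers differed between the cell types in their response to anti-CSF-1R by a median log2 difference of 4.13 (adjusted p = 9.75e-12, or 0.00464 with an estimated correlation), with the high level in 1 of the 2 anti-CSF-1R macrophage libraries. The p53 and DNA damage response list differed in its response to cisplatin by a median of 0.554 (adjusted p = 0.00127, or 0.0281).

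Other splits of the same libraries were tested for each count of called genes, with the decimal places decoded again for each split. For neutrophils of the combination against control, 1 of 35 splits, the real one, gave as many as its 98 genes (highest other 15). Without combination replicate 2 the count was 7. Without the groups 2 of 35 gave as many as the real 3 (highest other 4), so chance was not excluded. Nor was it for the other neutrophil comparisons. For anti-CSF-1R 16 of 35 splits gave as many as the real 2 (highest other 68), for cisplatin 15 of 35 as many as 6 (highest other 21), and for the combination against anti-CSF-1R 11 of 35 as many as 2 (highest other 12). For the combination against cisplatin 10 of 35 gave as many as 9, the highest being 306 when cisplatin replicate 1 and combination replicate 2 changed places, and for the interaction 22 of 31 gave as many as 1 (highest other 48). Nor was it excluded for cisplatin in macrophages, where 5 of 35 gave as many as 43 and the highest, 276, came when cisplatin replicate 2 and control replicate 1 changed places. Splits with many times the real count point to a structure of the samples, which was not examined further. For macrophages with anti-CSF-1R (303, highest other 102), the combination against cisplatin (352, highest other 11) and the combination against control (290, highest other 184), where the real split was 1 of 15, the splits were too few for a share under 0.05.

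Type I interferon-stimulated genes were higher in neutrophils of the combination than of control, by a median of 1.8 on the log2 scale. Without combination replicate 2, the lowest combination library still lay 0.513 above the highest control library in its mean log2 level, which argues against that library as the source. Decimal places that follow the groups are argued against by a median of 1.53 with places decoded without the groups. Macrophage RNA in the neutrophil sort is argued against by a median of -0.333 for the macrophage markers and by Rsad2, at 6709 in these neutrophils and 1641 in macrophages of the combination. The endpoint, confounded with cisplatin, stays open for a part. Levels at a shared endpoint, 0.96 ± 0.35 (SD, n = 4) in the combination and -0.3 ± 0.35 (SD, n = 3) with cisplatin, argue against it as the whole cause. An interferon response of neutrophils stays a hypothesis.

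Neutrophil markers were higher in macrophages with anti-CSF-1R, by a median of 1.2 against control. Neutrophil RNA or cells in the sort, as the whole cause, would raise 20 abundant markers by a like share of their neutrophil level. The upper quartile of these shares, 3.19%, was 10.6 times the lower, 0.301%, or 3.43 to 57.6 times with 1 library left out (added later). S100a8, S100a9 and Csf3r were higher by 1.19%, 1.17% and 2.30% of that level. What noise gives was not computed, so neutrophil RNA or cells stay open. Whether a lower share of macrophages raised all other cell types alike stays open, because unlike starting levels can give unlike log2 rises. Over both arms markers of 7 cell types differed by -0.539 (B cells) to 3.37 (eosinophils), with an SD of 1.36 (exact stratified permutation p = 0.00444). A changed share of single cell types stays open, and a change in the macrophages that remain under CSF-1R blockade may also contribute.

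Proliferation genes were lower in macrophages with anti-CSF-1R, by a median of -2.04 against control. Lower depth is argued against, because the deepest of the 4 libraries, combination replicate 1 with 3579216 reads, had a mean log2 level of -0.970, a difference of -0.883 from the lowest of 7 shallower libraries without the antibody. Less tumour cell RNA in the sort stays open: tumour and epithelial markers were 1.32 higher on the log2 scale with anti-CSF-1R over both arms, on 3 markers and with a level in 1 of the 2 anti-CSF-1R libraries (75 regroupings, exact stratified permutation p = 0.147). Fewer dividing macrophages under blockade of their growth factor receptor is a candidate explanation that stays untested.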

How the results depend on the processing

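Decoding without the groups, the most probable place for every cell, limma-voom and leaving out 2 neutrophil libraries were chosen after seeing the data. Other alternatives were chosen before. Of the calls for named genes, 153 of 155 kept their direction and stayed past the threshold with median-ratio rescaling, 143 of 155 with quantile normalisation, 147 of 155 with a pseudocount of 8, 146 of 155 without a filter, 95 of 115 with a filter of 50 and 133 of 155 with array weights. It was 104 of 115 with both cell types in one fit, 82 of 96 with only the groups compared and 923 of 1229 over the fits without 1 library. With other decimal places, 54 of 118 held with places decoded without the groups, 72 of 155 with the most probable place for every cell and 42 of 155 with limma-voom. Without the 2 neutrophil libraries 15 of 31 held. Of the list calls, 160 of 179 held without the groups, 84 of 182 with fry, 156 of 182 with quantile normalisation, 146 of 182 with the most probable place, 54 of 65 without the 2 neutrophil libraries and 843 of 984 over the fits without 1 library. Depth was 996270 to 7475274 reads per library, and differences of less than 1 read were not detectable at it. Needing 10 in 2 libraries was a choice and not a limit of depth, and counts without this filter are below. The planned count tests on whole reads were not run, because several places were possible for 68.0% of cells. No paired analysis was possible because the labels number no replicates. Where leaving out a library left 1 in its group, that library was assumed to vary like the other groups.

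Counts of called genes that moved by over 1.5 times are given by setting, with the count as reported in brackets, and the cause was not tested. With a pseudocount of 8, neutrophil counts were 5 (2) for anti-CSF-1R. Macrophage counts were 5 (0) for the combination against anti-CSF-1R and 6 (2) for the interaction. Between cell types 36 (16) differed for the combination against cisplatin and 54 (18) for anti-CSF-1R. With no filter, macrophage counts were 22 (0) for the combination against anti-CSF-1R and 11 (2) for the interaction. With a filter of 50, neutrophil counts were 1 (2) for anti-CSF-1R, 0 (2, with 537 at an unadjusted p under 0.05) for the combination against anti-CSF-1R and 63 (98) for the combination against control. Macrophage counts were 137 (303) for anti-CSF-1R and 19 (43) for cisplatin. Between cell types 4 (18) differed for anti-CSF-1R. In common were 11 (18). With quantile normalisation, neutrophil counts were 5 (2) for anti-CSF-1R, 1 (2) for the combination against anti-CSF-1R and 62 (98) for the combination against control. Macrophage counts were 197 (303) for anti-CSF-1R. Between cell types 52 (16) differed for the combination against cisplatin and 30 (18) for anti-CSF-1R. In common were 10 (18). With median-ratio rescaling, neutrophil counts were 4 (2) for anti-CSF-1R. With fits of only the 2 groups compared, macrophage counts were 83 (303) for anti-CSF-1R, 28 (43) for cisplatin, 609 (352) for the combination against cisplatin, 2 (0) for the combination against anti-CSF-1R and 192 (290) for the combination against control. In common were 11 (18). With a fit of both cell types together, neutrophil counts were 26 (2) for anti-CSF-1R, 14 (6) for cisplatin, 62 (9) for the combination against cisplatin, 12 (2) for the combination against anti-CSF-1R, 298 (98) for the combination against control and 2 (1) for the interaction. Macrophage counts were 13 (0) for the combination against anti-CSF-1R and 12 (2) for the interaction. In common were 29 (18). With array weights and robust eBayes, neutrophil counts were 24 (2) for anti-CSF-1R, 4 (9) for the combination against cisplatin, 1 (2) for the combination against anti-CSF-1R and 2 (1) for the interaction. Macrophage counts were 108 (303) for anti-CSF-1R, 90 (43) for cisplatin, 1618 (352) for the combination against cisplatin, 849 (290) for the combination against control and 7 (2) for the interaction. Between cell types 82 (16) differed for the combination against cisplatin. In common were 30 (18). With decoding without the groups, neutrophil counts were 0 (2, with 670 at an unadjusted p under 0.05) for anti-CSF-1R, 0 (6, with 598 at an unadjusted p under 0.05) for cisplatin, 0 (9, with 672 at an unadjusted p under 0.05) for the combination against cisplatin, 0 (2, with 758 at an unadjusted p under 0.05) for the combination against anti-CSF-1R, 3 (98) for the combination against control and 0 (1, with 386 at an unadjusted p under 0.05) for the interaction. Macrophage counts were 95 (303) for anti-CSF-1R, 2 (43) for cisplatin, 147 (352) for the combination against cisplatin, 98 (290) for the combination against control and 0 (2, with 631 at an unadjusted p under 0.05) for the interaction. Between cell types 0 (16, with 856 at an unadjusted p under 0.05) differed for the combination against cisplatin, 4 (18) for anti-CSF-1R and 0 (9, with 528 at an unadjusted p under 0.05) for cisplatin. In common were 1 (18). With the most probable place for every cell, neutrophil counts were 4 (2) for anti-CSF-1R, 16 (6) for cisplatin, 16 (9) for the combination against cisplatin, 6 (2) for the combination against anti-CSF-1R and 3 (1) for the interaction. Macrophage counts were 14 (43) for cisplatin, 37 (0) for the combination against anti-CSF-1R and 25 (2) for the interaction. Between cell types 31 (16) differed for the combination against cisplatin. With limma-voom on the decoded reads, neutrophil counts were 5 (9) for the combination against cisplatin and 11 (98) for the combination against control. Macrophage counts were 43 (303) for anti-CSF-1R, 19 (43) for cisplatin, 5 (0) for the combination against anti-CSF-1R, 182 (290) for the combination against control and 6 (2) for the interaction. Between cell types 68 (16) differed for the combination against cisplatin, 7 (18) for anti-CSF-1R and 4 (9) for cisplatin. In common were 0 (18). With neutrophil cisplatin replicate 2 and combination replicate 2 left out, neutrophil counts were 3 (9) for the combination against cisplatin, 1 (2) for the combination against anti-CSF-1R and 11 (98) for the combination against control. In common were 1 (18). With an estimated correlation, list calls were 24 (182). With fry, list calls were 108 (182). The split of neutrophil calls with anti-CSF-1R was 1 higher and 1 lower as reported. It was 4 and 1 after quantile normalisation and 3 and 1 after median-ratio rescaling. For neutrophils of the combination against anti-CSF-1R it was 1 and 1, and 1 and 0 after quantile normalisation. For the difference between cell types with cisplatin it was 5 and 4, and 8 and 2 after quantile normalisation.

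Leaving out each library in turn, called genes ranged in these intervals. For the difference between cell types they were 2 to 43 for anti-CSF-1R (lowest without macrophage anti-CSF-1R replicate 2, highest without macrophage anti-CSF-1R replicate 1), 3 to 17 for cisplatin (lowest without neutrophil cisplatin replicate 2, highest without macrophage cisplatin replicate 2) and 0 to 44 for the combination against cisplatin (lowest without macrophage combination replicate 1, highest without macrophage cisplatin replicate 2). For the sorted controls they were 4430 to 4835 (lowest without macrophage control replicate 2, highest without neutrophil control replicate 1). In macrophages they were 38 to 564 for anti-CSF-1R (lowest without anti-CSF-1R replicate 2, highest without control replicate 4), 17 to 133 for cisplatin (lowest without cisplatin replicate 3, highest without cisplatin replicate 2) and 0 to 9 for the combination against anti-CSF-1R (lowest without combination replicate 1, highest without anti-CSF-1R replicate 1). The range was 16 to 541 for the combination against cisplatin (lowest without combination replicate 2, highest without cisplatin replicate 2), 22 to 606 for the combination against control (lowest without combination replicate 2, highest without control replicate 4) and 1 to 6 for the interaction (lowest without combination replicate 2, highest without anti-CSF-1R replicate 1). In neutrophils they were 1 to 11 for anti-CSF-1R (lowest without control replicate 1, highest without control replicate 4), 1 to 8 for cisplatin (lowest without cisplatin replicate 2, highest without cisplatin replicate 1) and 0 to 2 for the combination against anti-CSF-1R (lowest without combination replicate 4, highest without combination replicate 1). The range was 4 to 8 for the combination against cisplatin (lowest without cisplatin replicate 1, highest without combination replicate 3), 7 to 163 for the combination against control (lowest without combination replicate 2, highest without control replicate 4) and 0 to 2 for the interaction (lowest without control replicate 2, highest without cisplatin replicate 3). Genes shared by the cell types ranged from 1 (without neutrophil control replicate 2 or neutrophil combination replicate 2) to 38 (without macrophage control replicate 4).

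Some directions turned, in each case past no threshold, and the cause was not tested. For Ep400 with places decoded without the groups the log2 fold change was -0.287 for cisplatin in macrophages, 0.438 for the macrophage interaction and -0.25 for the difference between cell types with cisplatin. For the chromatin organiser gene Satb1 in neutrophils it was 0.568 for the combination against anti-CSF-1R and 0.383 for the interaction with the most probable place for every cell, and 0.134 and 0.0342 with limma-voom. Lists turned without 1 library. In the neutrophil interaction, glycolysis and hypoxia turned without cisplatin replicate 2 (adjusted p = 0.589, 5.45e-05 to 0.589 over such fits). Type I interferon-stimulated genes (0.566, 4.34e-09 to 0.566) and interferon-gamma-responsive genes (0.709, 7.54e-07 to 0.709) turned there without control replicate 4. B cell and plasma cell markers turned in neutrophils of the combination against anti-CSF-1R without anti-CSF-1R replicate 1 (adjusted p = 0.792, 3.42e-05 to 0.792 over such fits). Neutrophil markers turned in the macrophage interaction without control replicate 3 (0.391, 0.00151 to 0.513). Type I interferon-stimulated genes turned in macrophages with anti-CSF-1R against control without anti-CSF-1R replicate 1 (0.726, 6.16e-08 to 0.726).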

Other observations

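The tests over both arms in the second paragraph were chosen only after the results were seen. In neutrophils with anti-CSF-1R, 11 of 11 genes of MHC class II presentation were higher (median 0.66, adjusted p = 0.00045, or 0.211 estimated). Of these 11, limma passed 0 over all genes and 2 over the list alone, with 3 at an unadjusted p under 0.05. Dendritic and B cell markers rose too, and over both arms the list did not pass (exact permutation adjusted p = 0.196). In macrophages of the combination against cisplatin, 23 of 25 immediate early and heat shock genes were higher (median 0.8, adjusted p = 3.56e-06, or 0.235 estimated). Of these 23, 3 passed over all genes and 9 over the list alone. There, 8 of 10 genes of neutrophil granule proteins were higher (median 1.33, adjusted p = 0.000674, or 0.0344 estimated). Of these 8, 3 passed over all genes and 5 over the list alone. For glycolysis and hypoxia genes, the response to adding anti-CSF-1R to cisplatin differed between the cell types by a median of 1.01 on the log2 scale (adjusted p = 7.37e-08, or 0.338 with an estimated correlation). Within neutrophils this list rests on cisplatin replicate 2, without which it did not pass for the combination against cisplatin (adjusted p = 0.0828), and within macrophages it did not pass without combination replicate 2 or cisplatin replicate 4 (adjusted p = 0.792 and 0.234).

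List levels were compared with and without anti-CSF-1R over both arms by an exact two-sided permutation test within arms. Regroupings were not decoded again, so such p-values may be too small. In macrophages 10 of 29 lists passed at an adjusted p of 0.0258: proliferation genes (-1.52 on the log2 scale) and macrophage markers (-0.45) were lower. Eosinophil markers (3.37), neutrophil markers (1.46), chemokines for T cells (1.11), neutrophil granule proteins (1.1), NF-kB targets (0.96), monocyte markers (0.85), neutrophil maturity genes (0.82) and lysosome genes (0.72) were higher. The smallest p that the 225 regroupings allow is 0.00444. In neutrophils, dendritic cell markers were higher with anti-CSF-1R (0.7, adjusted p = 0.0367 over 30 lists), while type I interferon-stimulated genes (1.09) and proliferation genes (-0.52) did not pass (adjusted p = 0.0643). With cisplatin, the p53 and DNA damage response list was higher in neutrophils (0.16, adjusted p = 0.0367), and in macrophages its difference was 0.55 (exact p = 0.00476, the smallest that 420 regroupings allow, adjusted p = 0.138 over 29 lists).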
